A study of Gallus gallus with 8 samples.

How the data were processed

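Poly(A) RNA was sequenced from migratory cranial neural crest cells of the chicken (Gallus gallus) in 8 libraries. Per the labels' protocols, neural tube pieces spanning rhombomeres 3 to 5 were isolated at Hamburger and Hamilton stage 8 and plated on fibronectin and poly-D-lysine. Recombinant DAN protein was added at 0, 1 or 10 µg/ml, per the labels' protocols. After a night in culture the tubes and remaining ectoderm were lifted off and the adherent cells were lysed, per the labels' protocols. The labels give 200 to 1000 cells per sample. Per the labels' protocols, cDNA was made with a SMART-seq v4 low-input kit, libraries with Nextera XT, and paired reads were taken on a NextSeq instrument. Such a kit amplifies full-length cDNA without molecular identifiers and without marking the strand, so reads from a gene and from an overlapping gene on the other strand cannot be told apart. PCR copies are counted as reads, so floors and counting intervals cover counting error only.

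The authors deposited whole-number read counts per Ensembl gene ID and library, not normalized. The authors also deposited RPKM values for the same genes and libraries. TopHat2 2.0.13, FastQC 0.10.1, edgeR 3.12.0, bedtools and the genome build galGal4 are named per the submitters' processing notes, with no role or order for each. How reads mapping to several places, mates and strands were treated is not given in the sources used here, so genes with near-identical copies carry that uncertainty. For 5133 genes above an RPKM of 5 in all libraries, the deposited count divided by the deposited RPKM scaled between libraries as TMM-adjusted library totals do, within 0.00963%. Gene lengths were taken from that ratio. Every row of the count table names a gene, and every value column was matched to a sample by the labels.

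Counts were tested with edgeR 4.0.16 in R 4.3.3. All 8 libraries entered 1 quasi-likelihood model with a mean per group, TMM factors and no replicate block, so the groups share 1 estimate of the spread. The filterByExpr function with its minimum count of 10 left 14085 of the 17108 genes. Contrasts were 10 µg/ml against untreated, 1 µg/ml against untreated, 10 against 1 µg/ml, and the mean of both doses against untreated. Tests were 2-sided, and a gene is called changed at a Benjamini-Hochberg adjusted p under 0.05 in that contrast. Normalised CPM values use TMM-adjusted totals. The log2 CPM values behind correlations and principal components carry a prior count of 2. The labels speak of 3 biological replicates per condition. The 2 untreated libraries analysed here are replicates 2 and 3, and both doses have replicates 1, 2 and 3.

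Pairs of libraries within a group differed far beyond sampling noise, with a chi-square per degree of freedom of 67.9 to 341 over genes, so each library was counted as 1 replicate. Total counts ran from 44338765 to 199084828 per library. A floor of 3 counts corresponds to 0.0143 to 0.0696 normalised CPM per library. Fold changes against a group with no count are lower bounds against 3 counts over the whole group. Where a group held 1 to 3 counts, the ratio of summed counts is given with an exact conditional (Clopper-Pearson) 95% interval.

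The files do not pair the Ensembl IDs with gene symbols, and 0 of the 17108 IDs matched the 25635 genes of the reference table used here. The 29 gene lists fixed before the data were examined (BMP targets and machinery, neural crest specifiers, adhesion, matrix, proteases, guidance, other cell types and others) were therefore not tested. The level of NBL1, the gene of DAN, is not analysed here for the same reason. The rule for named genes asked for symbols and for up to 12 genes each way per comparison. It was reduced to 2 genes that rose and 2 that fell: those with the largest fold changes among genes called at 10 µg/ml whose libraries do not overlap with the untreated ones. Without symbols, no cell type markers could be read, so the share of other cells in each dish is not analysed here.

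Both doses were compared with the same untreated libraries. To gauge what shared controls give alone, 20 sets of counts with no group effect were simulated from the gene means, library sizes and dispersions. Each gene had 1 dispersion for all libraries. The untreated pair differed more than the dosed pairs, with a chi-square per degree of freedom of 341 against 67.9 to 148. The simulated agreement may therefore be too low. After seeing the data, lists as long as the called ones were also taken from the simulated sets by smallest p. The script was tested on simulated counts with 200 changed genes per contrast. For 10 µg/ml against untreated (13859 genes run), 18% of genes changed by a factor of 2 and 59% of those changed by a factor of 4 were recovered, with 1 false call among 78. For 1 µg/ml against untreated (13841 genes run) the values were 16% and 57%, with 7 false calls among 80. For 10 against 1 µg/ml (13835 genes run) they were 19% and 71%, with 9 false calls among 99. For the mean of both doses (13853 genes run) they were 30% and 68%, with 15 false calls among 113.

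Alternatives chosen before the data were examined were other scalings (RLE factors, library size alone) and other filters (none, or 1 CPM in 6 libraries). Others were DESeq2 1.42.0, limma 3.58.1 with voom, with voom and sample quality weights and on log2(RPKM + 1), and a robust quasi-likelihood fit. The remaining ones were only the groups compared, a replicate block, an added minimum fold of 2 and each library left out in turn. After seeing the data, offsets correcting each library for trends with gene length, with abundance or with both (lowess span of 30%), a fit with both doses as 1 group and a fit with 1 separate untreated library for each dose were added.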

Results

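Messenger RNA was measured in chicken cranial neural crest cells that had migrated out of cultured hindbrain-level neural tubes in the presence of 0, 1 or 10 µg/ml of DAN. Neural crest cells are a migratory embryonic population that leaves the dorsal neural tube. DAN, the protein of the gene NBL1, is a secreted antagonist of bone morphogenetic proteins. The study asked, by its title, how DAN restrains invasion and keeps crest migration collective, and this experiment asked which genes of the migrating cells respond to it. There were 2 untreated libraries (replicates 2 and 3), 3 at 1 µg/ml and 3 at 10 µg/ml. The untreated libraries held 47523574 and 112505258 counts, those at 1 µg/ml 199084828, 70690016 and 81849420, and those at 10 µg/ml 118020458, 44338765 and 75906045. Between 15045 and 16239 genes had a count in a library, and 9300 to 9557 genes reached a deposited RPKM of 1.

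Cells grown with DAN were closer to each other across doses than the untreated libraries were to each other. Pearson's r of log2 CPM across genes was 0.945 between the untreated libraries, 0.977 to 0.982 within 1 µg/ml, 0.971 to 0.984 within 10 µg/ml, and 0.967 to 0.979 between the doses. Between untreated libraries and those with DAN it was 0.938 to 0.962 at 1 µg/ml and 0.922 to 0.951 at 10 µg/ml, so some dosed libraries were closer to an untreated one than the untreated ones to each other. Genes are not independent replicates, so these values describe libraries and carry no p. The first principal component, with 39.2% of the variance, ordered the groups by dose without overlap. Untreated libraries lay at -109 and -48.9, those at 1 µg/ml from 8.92 to 18.1, and those at 10 µg/ml from 34.3 to 46.3. The untreated libraries were parted from each other on the second component, at 47.5 and -76.2. Genes of the shortest length decile deviated by a median of -0.19 (log2) in untreated replicate 2 and 0.31 in untreated replicate 3, against -0.08 to 0.06 in the libraries with DAN.

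**Figure D1:**
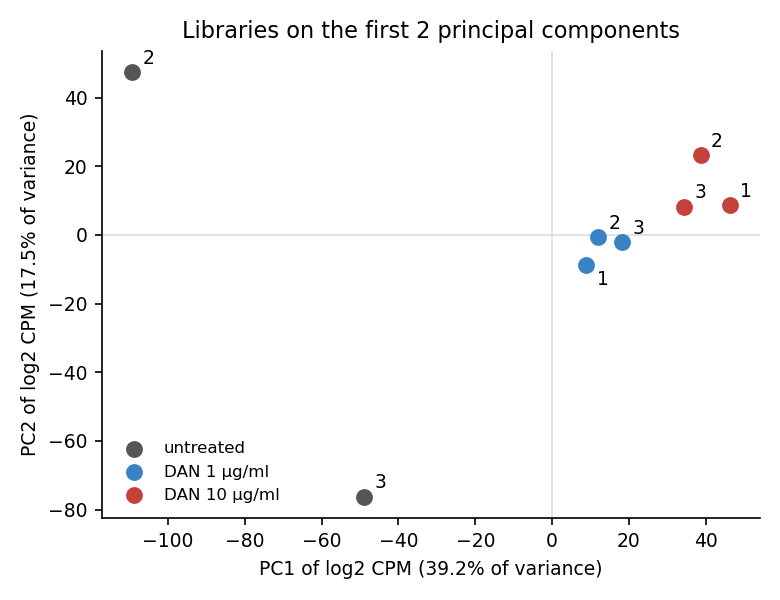
Each point is 1 of 8 libraries, placed by its first (39.2% of variance) and second (17.5%) principal component of log2 CPM over 14085 genes, with its replicate number. The 3 libraries at 10 µg/ml (34.3 to 46.3) lie beyond those at 1 µg/ml (8.92 to 18.1) on the first component, and the 2 untreated ones lie at -109 and -48.9.

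The first comparison asked which genes responded to the higher dose. At 10 µg/ml, 2304 of 14085 genes changed against untreated cells, of which 1018 rose and 1286 fell (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Of these, 547 rose and 946 fell at least 2-fold, and 201 rose and 306 fell at least 4-fold. The median change was a log2 fold change of 1.04 among genes that rose and -1.38 among genes that fell. Genes that rose were abundant, with a median of 26.7 CPM against 8.15 CPM for genes that fell and 7.25 CPM for all genes tested. These CPM are averages over all 8 libraries, so a rise with DAN raises them and a fall lowers them.

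The direction of change at 10 µg/ml differed with abundance and gene length. In the highest abundance decile (median 316 CPM) 170 genes rose and 74 fell, and in the third (median 1.07 CPM) 69 rose and 147 fell. The median log2 fold change of all genes ran from -0.36 in the lowest decile to 0.20 in the highest. Abundance was averaged over the same libraries as the change, so part of this link with direction is built in. Among the shortest genes (median 330 bases) 33 rose and 105 fell, and among the longest (median 6643 bases) 113 rose and 62 fell. Offsets that remove each library's trend with length or abundance even out such balances by construction. With abundance-corrected offsets 166 rose and 178 fell in the highest abundance decile, and 93 rose and 116 fell in the third. With length-corrected offsets 86 rose and 103 fell among the longest genes, and 69 rose and 99 fell among the shortest. The majority of rises in the highest and longest deciles was thus lost. How far the balances follow trends of whole libraries was not tested.

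**Figure D2:**
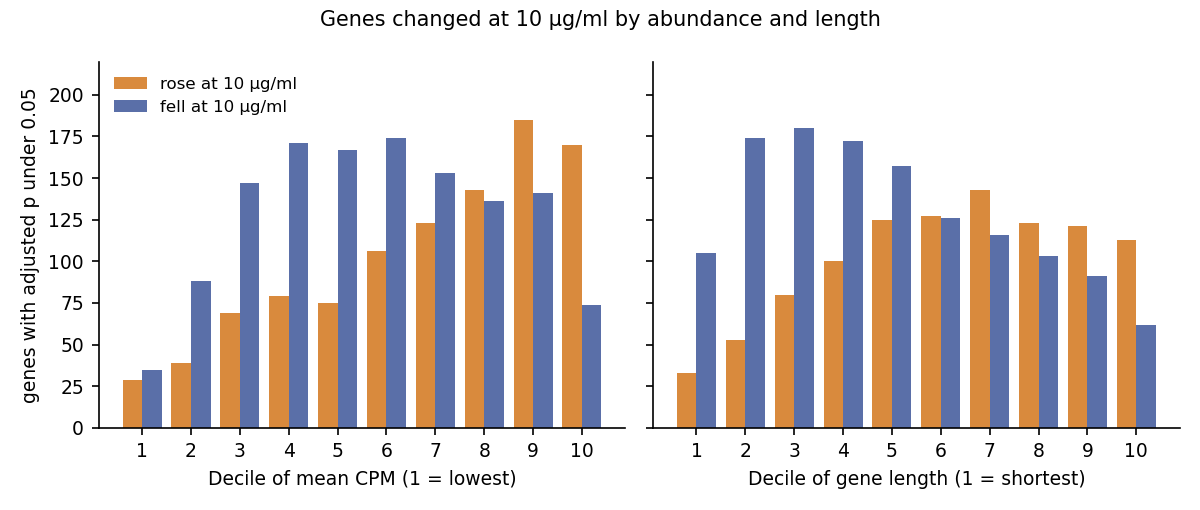
Bars give the number of genes called at 10 µg/ml against untreated that rose (orange) and fell (blue), in deciles of mean CPM and of gene length. Calls that fell outnumber those that rose up to the seventh abundance decile and up to the fifth length decile (157 against 125).

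Of the 2304 genes, 2301 had libraries at 10 µg/ml that all lay on 1 side of both untreated ones (1018 above, 1283 below). Genes called in these same libraries are nearly bound to be parted so. Over all genes tested 6688 (47.5%) were parted in this way, where chance gives 20% per gene for 3 libraries against 2. Genes are not independent, so a single grouping can lie far from 20% without an effect, and other groupings were not counted. The count of 2304 depended on single libraries: it was 5008 without untreated replicate 3 (2679 rose, 2329 fell, so more rose than fell), and 507, 1503 and 982 without replicates 1, 2 and 3 at 10 µg/ml. The fit without untreated replicate 3 takes its spread from the dosed libraries alone, since 1 untreated library remains. The count of 2304 became 3686 with DESeq2, 885 with only the groups compared in the fit and 1140 with a replicate block. Voom quality weights gave 236 (22 rose, 214 fell). They weighted the untreated libraries at 0.334 and 0.329 and the others at 1.02 to 2.35. The untreated libraries thus varied more than the 1 shared spread of the main fit assumes. In every comparison against untreated the main fit's p may therefore be too small and its count of calls too high.

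The genes with the largest changes at 10 µg/ml were low or absent in 1 of the groups. They are given by Ensembl ID, since the files do not pair IDs with symbols. ENSGALG00000014994 had no count in either untreated library, 2.58 ± 1.56 CPM (SD, n = 3) at 1 µg/ml and 8.67 ± 2.38 CPM (SD, n = 3) at 10 µg/ml. That was at least 136-fold higher at 1 µg/ml and at least 455-fold higher at 10 µg/ml than the floor of 3 counts over the untreated group. ENSGALG00000028915 likewise had no count in untreated cells, 0.621 ± 0.288 CPM (SD, n = 3) at 1 µg/ml and 1.58 ± 0.626 CPM (SD, n = 3) at 10 µg/ml. It was at least 32.6-fold and at least 82.9-fold higher at these doses. Both genes were called at 10 µg/ml (adjusted p = 0.00388 and 0.00434, edgeR) and at 1 µg/ml (both adjusted p = 0.0309, edgeR). They were above both untreated libraries in 6 of 6 libraries with DAN, which for the 3 at 10 µg/ml was fixed by the rule that chose them.

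ENSGALG00000028434 fell from 0.893 ± 0.710 CPM (SD, n = 2) in untreated cells to 1 count over the 3 libraries at 10 µg/ml, a level 168-fold lower (95% counting interval 29.6 to 6707; adjusted p = 0.00702, edgeR). At 1 µg/ml it stood at 0.155 ± 0.0876 CPM (SD, n = 3), 5.76-fold below untreated, which did not pass the test (adjusted p = 0.0979, edgeR). Its log2 fold change at 1 µg/ml, -2.52, was -1.35 without untreated replicate 2 and -3.17 without untreated replicate 3, where it was called (adjusted p = 0.0244, edgeR), as it was with DESeq2 (adjusted p = 0.0485); over all alternatives the adjusted p ran from 0.0244 to 0.389. ENSGALG00000027798 fell from 0.464 ± 0.144 CPM (SD, n = 2) to 1 count at 10 µg/ml, 112-fold lower (interval 19.6 to 4490; adjusted p = 0.00678, edgeR). Its level of 0.152 ± 0.0437 CPM (SD, n = 3) at 1 µg/ml was 3.06-fold below untreated and did not pass the test (adjusted p = 0.184, edgeR), although limma on log2(RPKM + 1) called it (adjusted p = 0.0409; 0.0409 to 0.437 over all alternatives). With quality weights neither gene that rose was called at 10 µg/ml (adjusted p = 0.172 and 0.136, limma), while over all alternatives the adjusted p ran from 4.1e-12 to 0.172 and from 1.35e-07 to 0.136. At 1 µg/ml their calls ended under 8 of 23 and 10 of 22 alternatives.

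**Figure D3:**
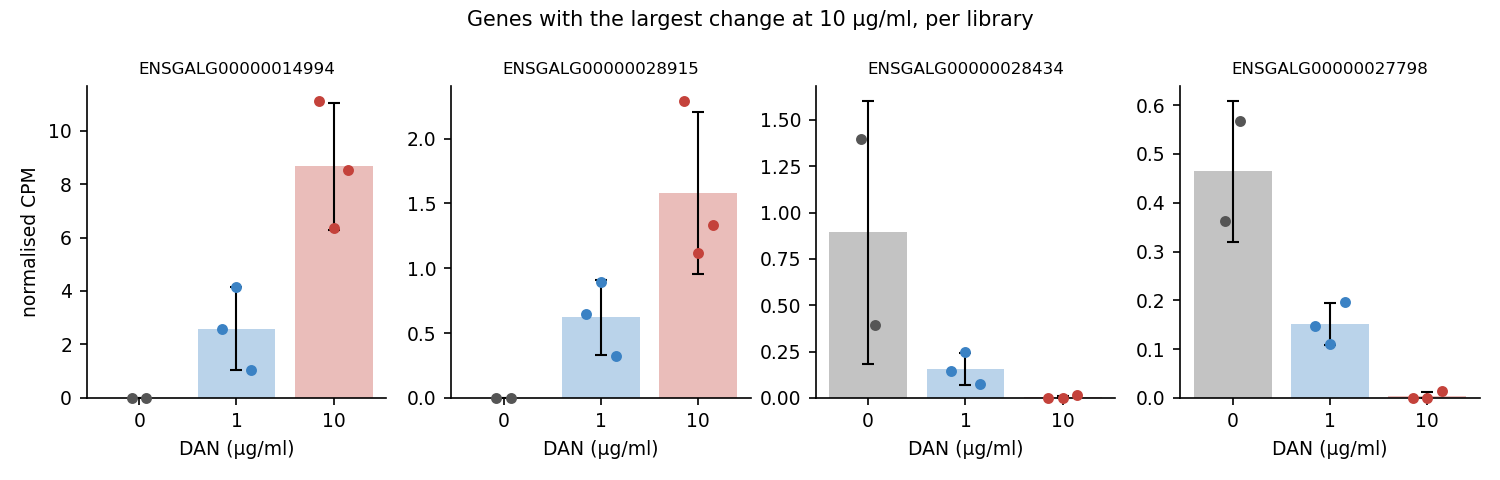
Points are normalised CPM per library, bars the group mean and whiskers the SD, at 0 (n = 2), 1 (n = 3) and 10 µg/ml (n = 3) of DAN, each panel on its own axis. The 2 genes on the left had no count without DAN, and the 2 on the right had 1 count each over the libraries at 10 µg/ml.

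The comparison at the lower dose asked whether 1 µg/ml was enough for a response. At 1 µg/ml, 396 of 14085 genes changed against untreated cells, of which 213 rose and 183 fell (edgeR). Among them 147 rose and 140 fell at least 2-fold, and 57 rose and 41 fell at least 4-fold. The median log2 fold change was 1.23 for genes that rose and -1.41 for genes that fell. Before adjustment 3656 genes had a p under 0.05. Scaling to library size alone gave 411 genes that rose and 182 that fell, and length-corrected offsets 238 and 326, so which direction held more genes depended on the scaling.

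The count of 396 changed with every library left out. It was 825 without untreated replicate 2 and 3469 without untreated replicate 3; it was 1, 3 and 1 without replicates 1, 2 and 3 at 1 µg/ml, and 0, 15 and 0 without replicates 1, 2 and 3 at 10 µg/ml, which share the estimate of the spread. With 1 untreated library left, the spread comes from the dosed libraries alone. DESeq2 called 2157 genes, voom 517, voom with quality weights 0, the fit with only these groups 0 and the fit with a replicate block 2.

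Most genes called at the higher dose lay on the same side of untreated at the lower one, which the shared untreated libraries favour without any effect. Of the 1018 genes that rose at 10 µg/ml, 1016 lay above untreated at 1 µg/ml, with a median log2 fold change of 0.82 against 1.04 at 10 µg/ml. Of the 1286 that fell, 1284 lay below untreated at 1 µg/ml, with a median of -0.89 against -1.38. The shares, 99.8% for both lists, compare with 92.8% and 87.0% for lists of these sizes with the smallest p in simulated counts with no effect. The simulation gave untreated libraries no more spread than dosed ones, so these simulated shares may be too low. The change was further from 0 at 10 than at 1 µg/ml for 849 genes that rose and 1178 that fell, in lists chosen at 10 µg/ml. In the lists chosen at 1 µg/ml it was further at 10 µg/ml for 107 of 213 genes that rose (median 1.23 at both doses) and 114 of 183 that fell (median -1.56 at 10 µg/ml and -1.41 at 1 µg/ml). At both doses 195 genes rose and 164 fell, and 0 genes were called in opposite directions.

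The doses share their untreated libraries, so some agreement arises without any effect. Independent lists of these sizes would share 15.4 genes that rose and 16.7 that fell. In simulated counts with no effect almost no gene was called, with a mean of 0.05 and 0 shared calls, so lists as long as the real ones were taken there by smallest p. These shared a mean of 144 genes that rose (130 to 157 in 20 simulations) and 99.0 that fell (85 to 115), against 195 and 164 observed. Across all genes Pearson's r of the fold changes was 0.850 (0.621 simulated), Spearman's rho 0.836 (0.561 simulated) and the share with the same sign 83.6% (70.5% simulated). The covariance was 0.907 against 0.203 simulated, a difference of 0.704. It was 1.49 without untreated replicate 2 and 2.47 without untreated replicate 3. With 2 untreated libraries the controls could not be split into parts of at least 2 libraries, so part of the excess in shared calls may come from them. The simulated values may also be too low, since the untreated pair varied more than the simulation allowed. With 1 untreated library for each dose, tried after seeing the data, no control is shared. Pearson's r was then 0.302 and 0.308 for the 2 ways of assigning them, the share with the same sign 60.6% and 63.8%, and the covariance 0.564 and 0.592. Of the 1018 genes that rose and the 1286 that fell at 10 µg/ml with the smallest p in these fits, 72.3% and 72.0% had the same sign at 1 µg/ml in 1 assignment, and 81.1% and 77.8% in the other.

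**Figure D4:**
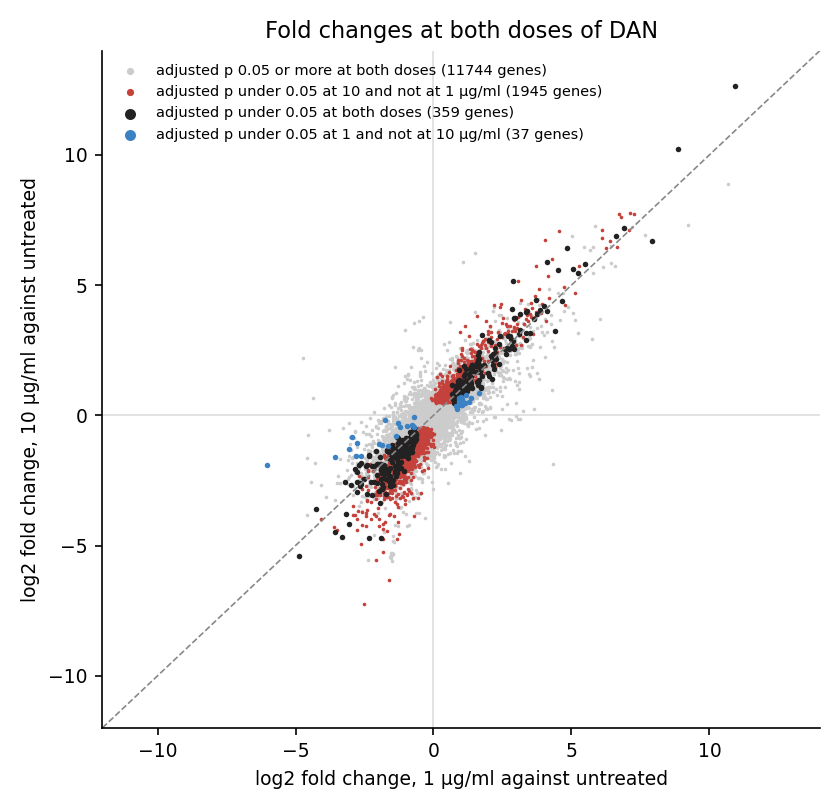
Each point is 1 of 14085 genes, with its log2 fold change against untreated at 1 µg/ml (horizontal) and at 10 µg/ml (vertical); colours give the calls and the dashed line equal change. The 359 genes called at both doses lie in the upper right (195) and the lower left (164), around the line.

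The direct comparison of the doses asked whether more DAN changed the cells further. No single gene passed at 10 against 1 µg/ml: 0 of 14085 genes had an adjusted p under 0.05 in edgeR, and the smallest was 0.303. Before adjustment 1605 genes (11.4%) had a p under 0.05, of which 686 were higher and 919 lower at 10 µg/ml. Among them were 482 of the 1286 genes that fell at 10 µg/ml against untreated and 232 of the 1018 that rose, and these lists share the libraries at 10 µg/ml with this comparison. The spread of the main fit includes that of the untreated pair, which may make this comparison too strict. With only the 2 dose groups in the fit, 2829 of 13417 genes had a p under 0.05 before adjustment (edgeR), and 0 were called. For the genes given by ID, ENSGALG00000014994 was 3.36-fold higher (adjusted p = 0.333, edgeR) and ENSGALG00000028915 2.54-fold higher (adjusted p = 0.379, edgeR) at 10 than at 1 µg/ml. ENSGALG00000028434 was 33.6-fold lower (95% counting interval 5.79 to 1353) and ENSGALG00000027798 34.3-fold lower (5.90 to 1377), from 1 count each at 10 µg/ml, and neither passed (adjusted p = 0.304 and 0.303, edgeR). With DESeq2 ENSGALG00000014994 and ENSGALG00000028434 were called (adjusted p = 0.0160 and 0.0412), where the adjusted p over all alternatives ran up to 0.906 for both. DESeq2 called 248 genes (91 higher, 157 lower), and voom, voom with quality weights and limma on log2(RPKM + 1) called 0; without replicate 2 at 10 µg/ml edgeR called 1.

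Averaged over both doses, 2303 of 14085 genes differed between cells with DAN and untreated cells, of which 973 rose and 1330 fell (edgeR). At least 2-fold changes were found for 440 genes that rose and 862 that fell, and the median log2 fold changes were 0.93 and -1.21. There were 3 genes with 3 or fewer counts in both untreated libraries and at least 0.5 CPM in all 6 with DAN, of which 1 was ENSGALG00000014994, and 0 genes with the reverse pattern. The count was 4816 without untreated replicate 3 (2519 rose, 2297 fell, so more rose than fell), 1501 and 1375 without replicates 2 and 3 at 1 µg/ml, and 1057 and 1294 without replicates 1 and 3 at 10 µg/ml. DESeq2 called 3651 genes, voom with quality weights 0, and the fit with a replicate block 973. Without untreated replicate 3 the spread comes from the dosed libraries alone.

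A set of 18 genes was nearly absent from replicate 2 at 10 µg/ml and expressed in the other 7 libraries. These genes, chosen after their values were seen, held 8 counts in all in that library and 13 of them none, where their levels elsewhere would give 113648. In the other libraries their median ran from 2.49 to 1090 CPM, and no gene had fewer than 121 counts in any of them. None of the 18 was called at 10 µg/ml against untreated or against 1 µg/ml (0 genes, edgeR).

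**Figure D5:**
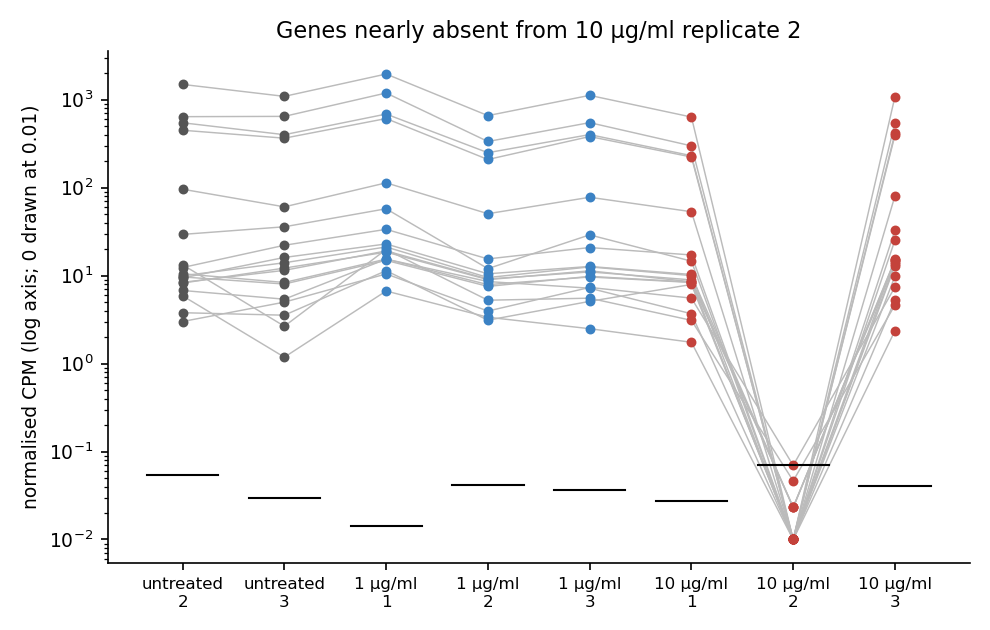
Lines join the normalised CPM (log axis, 0 drawn at 0.01) of each of 18 genes across the 8 libraries, coloured by group, and black bars mark 3 counts in each library. All 18 genes lie at or under 3 counts in replicate 2 at 10 µg/ml and at 121 counts or more in each of the other 7 libraries.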

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

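Offsets corrected for gene length, abundance or both, the fit with both doses as 1 group and separate controls for each dose were chosen after seeing the data. The planned tests of the 29 gene lists with all their alternatives were not run, since no ID was paired with a symbol, and the fit with only the groups compared gives nothing separate for the mean of both doses. Of the genes called by edgeR at either dose or for the mean, none was called in the opposite direction (0 genes) under the alternatives that gave gene calls, which excludes the separate controls. With DESeq2 the counts were 3686 at 10 µg/ml, 2157 at 1 µg/ml, 248 for 10 against 1 µg/ml and 3651 for the mean of both doses. With voom quality weights they were 236, 0, 0 and 0, and with only the groups compared 885 at 10 µg/ml and 0 at 1 µg/ml. The cause was not tested in either case. An added minimum fold of 2 removed calls by construction, leaving 1493 at 10 µg/ml and 1302 for the mean. At 1 µg/ml (396 genes) the count was 664 with the stricter filter, 706 on log2(RPKM + 1) and 757 with abundance-corrected offsets, and the cause was not tested. Other scalings, filters and the robust fit stayed within 1.5 times. Library size alone moved the median log2 fold change of all genes at 10 µg/ml from -0.02 to -0.13.

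Leaving out each library in turn gave 507 to 5008 genes at 10 µg/ml, 0 to 3469 at 1 µg/ml, 0 to 1 for 10 against 1 µg/ml, 1057 to 4816 for the mean of both doses, and a covariance of 0.868 to 2.47. The covariance, 0.907 with shared controls, was 0.564 and 0.592 with 1 separate untreated library for each dose, where by construction no control is shared. Without 1 untreated library the other is assumed to vary like the dosed groups. Of the genes called at 10 µg/ml, 52.3% and 88.5% remained called without untreated replicates 2 and 3, 22.0%, 60.7% and 42.0% without replicates 1, 2 and 3 at 10 µg/ml, and 70.4% to 73.3% without 1 library at 1 µg/ml. Of the log2 fold changes of the 4 genes given by ID, none reversed, 239 kept their side of the threshold, 20 lost it and 5 gained it.

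The labels give the groups the same replicate numbers without saying that they mark a shared day. Same-numbered libraries correlated at -0.025 to 0.185 after removing group means, not all above 0.1. Yet 7 of 8 libraries correlated best with their own number. Whether the numbers mark something shared is therefore not settled, and the main fit has no block. With a replicate block the counts were 1140 at 10 µg/ml (486 rose, 654 fell), 2 at 1 µg/ml, 0 for 10 against 1 µg/ml and 973 for the mean of both doses. Thinning all libraries to 44338765 counts gave 2295 genes at 10 µg/ml. Depth limits the genes near the floor, of 0.0143 to 0.0696 CPM per library.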

Other observations

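The tests of low-count sampling and of a dosed library standing in for an untreated one were chosen after the results were seen, and all patterns below were first noticed in these data. Genes expected at 100 or more counts but found at 3 or fewer were not unique to replicate 2 at 10 µg/ml (18 genes): untreated replicate 2 lacked 15, untreated replicate 3 lacked 8, replicate 3 at 1 µg/ml lacked 2, and the other 4 libraries lacked 0.

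The untreated libraries lay on 1 side of all 6 with DAN on the first principal component, although their own correlation (0.945) was within the range between untreated and dosed libraries (0.922 to 0.962). Only 1 of the 28 splits of the libraries into 2 and 6, the real one, called as many genes (1815 against at most 23 in another split). That is the smallest share 28 splits allow, for a pattern first noticed in these data. Every other split puts an untreated library in 1 group with dosed ones, which can widen the fitted spread. The splits therefore argue against chance without excluding it. As the whole cause, the tables argue against a smooth trend with gene length (93.1% of genes called at 10 µg/ml stayed called with length-corrected offsets). They also argue against sequencing depth (93.0% after thinning). The same holds for low-level background reads in untreated cells, as far as these follow abundance smoothly (88.3% of those that fell stayed called). Bias that differs between genes of like length or abundance is not removed by such offsets and was not tested. The 500 most changed genes against 1 untreated library kept 18.1% to 68.7% of their change against the other. Against a dosed stand-in they kept at most 16.9%, each share measured in 1 dosed library. The 18.1% and 16.9% come from different picks. In the pick that kept 18.1% the stand-ins kept at most 7.39%, and in the pick with the 16.9% the other untreated library kept 68.7%. In each of the 12 picks the share kept was above those of its own stand-ins. For the genes picked, this argues against 1 aberrant untreated library as the whole cause. How far such a library added to the pattern stays open, since 18.1% and 68.7% lie on both sides of the limits set. The action of DAN and an unrecorded handling difference between dishes with and without DAN may each be the source.

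Genes called at 10 µg/ml, in lists chosen at that dose, mostly changed further at 10 than at 1 µg/ml. Those that rose at 1 µg/ml had a median of 1.23 (log2) at both doses. Those that fell at 1 µg/ml had a median of -1.56 at 10 µg/ml and -1.41 at 1 µg/ml. Between the doses edgeR called 0 genes (DESeq2 called 248, and edgeR 1 without replicate 2 at 10 µg/ml). A graded response to dose is a hypothesis: genes picked between 1 library at 1 µg/ml and 1 untreated library changed 1.40 times as much at 10 as at 1 µg/ml in libraries not used to pick them (median of 6 splits; 1.25 to 1.45). Each of the 10 splits of the 6 dosed libraries into 3 and 3 called 0 genes, the real split and the highest other included (10 of 10 as large), which tests nothing since the real count is 0, and 10 splits are too few for a share under 0.05. Both changes are read against the same untreated library, so a handling difference that grew with the dose may give the same ratio.

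The 18 genes nearly absent from replicate 2 at 10 µg/ml are not explained by sampling of low counts, since 0 such genes arose in that library in any of 100 simulations. In the other 7 libraries they moved together, with a mean pairwise correlation of 0.657. That was at percentile 100 of 1000 random sets matched on abundance, whose median was -0.013. Some of the 18 had nearly equal CPM in every library. Near-identical copies that share reads would also raise the correlation, and the random sets were not matched for this. With that limit, such values would follow from 1 shared source of these transcripts that this library lacks and the others hold in varying amounts. A candidate source is genes carried by only 1 sex, such as those of the W chromosome of female birds, with that dish holding cells of male embryos alone. The IDs were not placed on chromosomes here, so this stays an untested hypothesis, and a strain difference or loss of a chromosome segment also stays open.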
